A study of Mus musculus with 6 samples.

How the data were processed

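Single cells of wild-type mice were profiled with a droplet 3′ kit (10x Genomics Chromium) in 6 libraries, 1 per group. Each library came from young or aged mice and from 1 of 3 contexts, namely bone marrow at steady state, bone marrow 24 h after occlusion of the middle cerebral artery (an experimental stroke), and blood at steady state. Per the labels, the bone marrow cells had been enriched for Gr1+ and for c-kit+ fractions, and the blood cells had been sorted as CD11b+ Ly6G+ and CD11b+ Ly6G− fractions, so the gates help to set the share of every cell class. The labels give neither the ages nor the number of mice behind a library.

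The authors deposited 1 table of raw UMI counts per gene and cell, with 23016 genes and 28055 barcodes, and the barcode names carry the library. Cell Ranger 3.0.2, UMI-tools, STAR 2.5.3a, Subread and featureCounts 1.6.4 and the build GRCm38 (mm10) are named, with no role or order, per the submitters' processing notes. Which tool made which library's counts, and how reads that match several genes were counted, is not given in the sources used here. The deposited cells had already been filtered: no barcode had fewer than 201 genes, and the highest mitochondrial share was 4.91% to 4.99% in the steady-state libraries of bone marrow and 9.90% to 9.95% in those after stroke. The counts sum to between 10208699 UMIs (young blood) and 72743805 UMIs (young bone marrow at steady state) per library, and the number of cells in a class sets the precision of its sums.

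Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with an own implementation of the Scrublet score (simulated pairs at a ratio of 2 to the cells, prior 0.06), and cells above 0.25 were left out. This removed 3.75% and 3.08% of the young and aged cells of steady-state marrow, 2.96% and 2.60% of the blood cells, and 0.397% and 0.603% of the cells after stroke. Only 7.46% and 13.0% of the simulated doublets of the young and aged stroke libraries exceeded the score, against 37.9% to 53.7% in the other libraries, so doublets remain in the stroke libraries. Each context was clustered on its own (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, figures with matplotlib 3.10.9).

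Clusters were named from markers of 18 cell classes that, with the gene lists, the tests and the first set of alternatives, had been fixed before the data were examined. The scoring rule that turns the markers into names was not fixed then: its thresholds and the rule for neutrophil stages were set, and revised several times, after cluster tables had been seen. A cluster first took the name of the class with the highest mean log2 fold of its 5 highest markers over the median cluster (pseudocount 20 CPM). It needed a score of at least 1.5 and at least 3 markers, and no unrelated lineage at 0.6 times that score or more. Clusters of low UMI count without leading markers of their lineage stayed unnamed. Within the neutrophil and progenitor lineages, stage markers against the lineage's other clusters could change the name, as in steady-state cluster 9. A cluster whose 10 leading genes held more markers of another class became unnamed, as did steady-state clusters 0, 11 and 17. The unnamed share was 23.7% and 22.0% of the young and aged cells of steady-state marrow, 30.4% and 28.5% after stroke, and 9.50% and 5.31% in blood. All names below stand for "like" the class.

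No cluster of steady-state marrow was named mature neutrophil. In that context 4 unnamed clusters led by mature markers hold 472 young cells (5.97%) and 427 aged cells (6.90%). The mature comparison of age planned over 6 libraries was therefore fitted on the 4 libraries with a mature class, a change made after the data were seen, and the comparison that joins immature and mature cells of all 6 libraries, listed from the start as another choice, is given beside it. The planned contrasts of stroke against steady state and of blood against marrow in mature cells were not made, and the joined class stands in for the first of them.

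Raw counts were summed per library and class, for classes with at least 30 cells in every library of the fit, and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr; R 4.3.3, limma 3.58.1) in an additive model of context and age, with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. With 1 library per group, the residual spread of this model is how far an age or stroke difference varies between contexts or ages. The p-values measure the average effect against that variation and against a spread pooled over genes, not against biological replicates. A small p therefore does not mean that a gene's pairs of libraries agreed: Gm6977 in mature and Olfm4 in dividing cells passed with pairs far apart. The fits of 4 libraries have 1 residual degree of freedom and the fits of 6 have 2. On simulated counts the age fits called 42% (mature), 88% (joined), 71% (immature) and 76% (dividing) of genes changed 2-fold, and the stroke fits 79% (immature) and 81% (dividing). Beside the changed genes, the age fits also called 3, 10, 8 and 12 unchanged genes in the same order, and the stroke fits 7 and 0. The simulated counts followed the additive model, with the dispersion trend of the same fit and changes only in genes above a minimum mean count. They held no age or stroke effects specific to a context or library, so these numbers need not hold for the real data. In the real data the age fits called 3, 5, 12 and 48 genes.

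Sets were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, over 31 fixed lists of 586 genes in all, with BH adjustment over the lists. The preset value is an assumption of nearly independent members, so p-values of lists whose genes move together can be too small. Single pairs of libraries were described without p-values, as log2 ratios of CPM with a pseudocount of 1 CPM, and by the percentile of a list's median among 10000 random lists of matched expression. The intervals of these ratios are exact binomial 95% intervals from the counts of both libraries, without the pseudocount. A ratio with few counts can therefore lie near an end of its interval. Shares have exact Clopper-Pearson 95% intervals. Intervals and upper limits cover counting error only.

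The text names, for each fit, the 12 largest changes of each direction among genes past the threshold that had the same sign in every pair of libraries and a mean CPM of at least 20, all genes of the list of maturation and release receptors, and the 4 members with the smallest p of each other list described. Where fewer than 6 genes of a direction passed, those with the smallest p fill up to 6, as not passing. For single pairs it takes the 6 largest ratios of each direction among genes with at least 50 counts and 50 CPM. Not every gene the rule allows is named. Sex-linked, haemoglobin, immunoglobulin and unnamed gene models were kept out of these tops. Gm6977, Cd38, Trim37, C1qa, C1qb, Prg2 in monocytes and Fkbp5 in dividing cells after stroke fall outside the rule and were chosen after their values had been seen.

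Alternatives were DESeq2 size factors within edgeR, DESeq2 1.42.0 (Wald test), no filter on low counts, doublets kept, minimum UMIs of 1000 or 200, resolutions of 0.5 and 2, cells thinned to 2000 UMIs, no context term, each library left out, and list members with a mean CPM of at least 20. Chosen after seeing the data were the age comparisons in stem and progenitor cells and in classical monocytes, the fits without granule-rich cells, without an interferon-rich blood cluster and with equal limits on cells, and a fit without genes that share sequence. For the last, every 31-base word of the final 400 bases of each gene's transcripts was looked up in all other genes of the annotation (GENCODE mouse M21, GRCm38). By this measure 46.2% of annotated genes share at least 1 word with a gene that does not overlap them. A gene with such copies can lose or gain UMIs with the way multiply matching reads are counted, and its values are uncertain. Positions are from the same annotation.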

Results

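Transcripts of single cells were counted in young and aged mice to compare the formation of neutrophils at steady state and after stroke. The 6 libraries were young and aged bone marrow at steady state, young and aged bone marrow 24 h after occlusion of the middle cerebral artery, and young and aged blood at steady state. Each group had 1 library, so there were no replicates and no difference below was checked against other animals. The deposited cells numbered 8213 (young) and 6389 (aged) in steady-state marrow, 2858 and 3017 in marrow after stroke, and 2236 and 5342 in blood. In the same order the libraries held 72743805 and 68455949 UMIs, 31015927 and 43789122 UMIs, and 10208699 and 34948850 UMIs. The median cell had 7743 and 9150 UMIs in steady-state marrow, 3811 and 9302 after stroke, and 4004 and 4682 in blood. After filtering, 7905, 6192, 2256, 2639, 1969 and 5203 cells were kept.

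The first question was which stages of the neutrophil lineage each library held. Mature neutrophil-like cells made up 72.9% of the young blood cells (exact 95% interval 70.9% to 74.9%) and 58.9% of the aged ones (57.5% to 60.2%). In marrow after stroke they made up 8.25% (7.14% to 9.46%) in young and 5.34% (4.52% to 6.27%) in aged mice. No cluster of steady-state marrow took that name under the naming rule, while 4 unnamed clusters led by mature markers held 472 (5.97%) of the young and 427 (6.90%) of the aged cells there. Immature neutrophil-like cells made up 9.51% (8.88% to 10.2%) of young and 10.1% (9.39% to 10.9%) of aged steady-state marrow, and 7.54% (6.48% to 8.70%) and 12% (10.8% to 13.3%) after stroke. Dividing pre-neutrophil-like cells, the proliferating committed precursors, made up 6.28% and 5.44% at steady state and 2.62% and 3.37% after stroke. An unnamed precursor-like cluster led by Fcnb and Camp held another 354 young (4.48%) and 187 aged cells (3.02%) at steady state. After stroke a similar unnamed cluster held 20 young (0.89%) and 81 aged cells (3.07%), so these shares depend on the naming rule. Stem and progenitor-like cells made up 10.3% (9.60% to 11%) of young and 13.6% (12.8% to 14.5%) of aged steady-state marrow. Classical monocyte-like cells made up 14.1% (12.6% to 15.6%) of young and 7.62% (6.63% to 8.70%) of aged marrow after stroke. Non-classical monocyte-like cells made up 2.54% (1.89% to 3.33%) of young and 10.8% (9.97% to 11.7%) of aged blood. The Gr1+ and c-kit+ enrichment of marrow and the Ly6G+ and Ly6G− sorts of blood can set each of these shares, and no share was tested between groups.

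**Figure D1:**
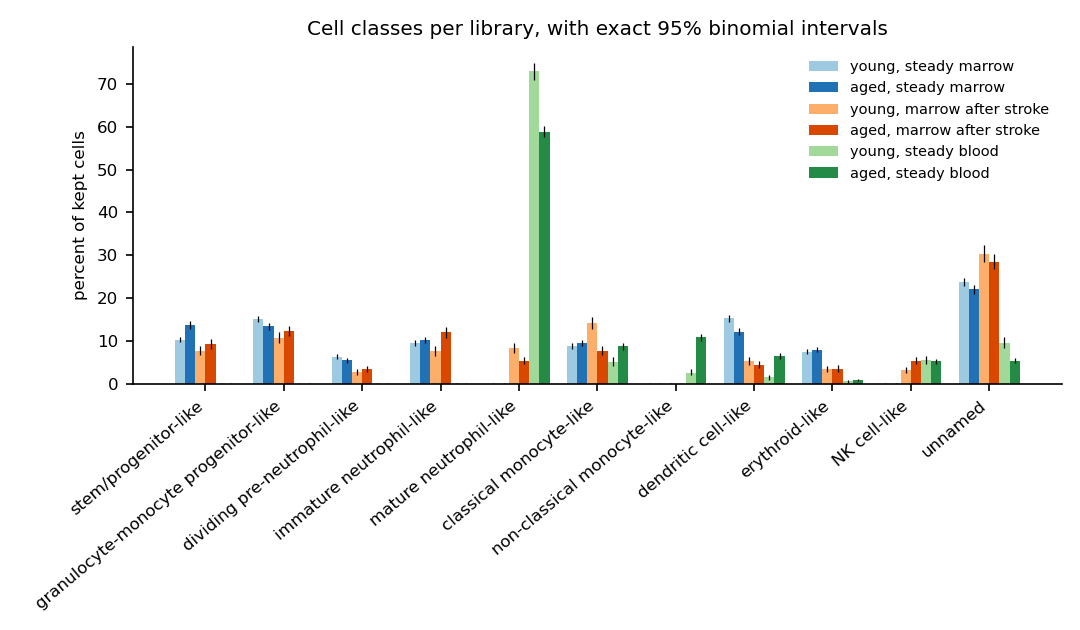
Percent of kept cells (vertical axis) in each named cell class (horizontal axis), with 1 bar per library and exact 95% binomial intervals that cover counting error only. The mature neutrophil-like bars reach 72.9% in young and 58.9% in aged blood and are at 0 in both libraries of steady-state marrow, where no cluster took that name.

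Positions of the genes that recur below are on GRCm38. The lactoferrin gene Ltf lies on chromosome 9 from 111019271 to 111042767, and Steap4, which encodes a metalloreductase, on chromosome 5 from 7960457 to 7982213. The interferon-stimulated gene Ifi27l2a lies on chromosome 12 from 103442167 to 103443680, and Oasl2 on chromosome 5 from 114896936 to 114912234. Lipg, which encodes endothelial lipase, lies on chromosome 18 from 74939322 to 74961263. The decoy receptor gene Il1r2 lies on chromosome 1 from 40074079 to 40125231, the chemokine receptor gene Cxcr2 on the same chromosome from 74153989 to 74161246, and the myeloperoxidase gene Mpo on chromosome 11 from 87793581 to 87804413. Oasl2, Ifi27l2a and Cxcr2 share 1.95%, 7.03% and 11.5% of their 3′ words with other genes, so their values are uncertain. All of the genes above are annotated as protein-coding, and the 3′ counts read the end of their transcripts.

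The second question was how mature neutrophils differed with age. In the 4 libraries with a mature class, 1 gene was higher and 2 were lower in aged cells among 8982 tested (edgeR quasi-likelihood test, adjusted p below the threshold). Its p-values set the average difference against its variation between contexts and against a spread pooled over genes, not against replicates. Ltf, a protein of the specific granules, rose by 1.55 ± 0.24 on the log2 scale (estimate ± SE, adjusted p = 0.0442), with ratios of 1.48 after stroke and 0.96 in blood, both below the fitted value. Its UMIs sat in few cells: 10 cells held 67.2% and 64.1% of the 598 young and 1441 aged UMIs after stroke, and 1 aged blood cell held 82.9% of 41 UMIs. Without the 10 cells per library richest in granule transcripts the value was 1.18 ± 0.30 (adjusted p = 0.185), past the threshold no longer. Steap4 fell by 1.69 on the log2 scale (SE 0.25, adjusted p = 0.0338). Its ratio was −2.0 after stroke (interval −3.56 to −0.96, from 7 aged and 36 young UMIs) and −1.57 in blood (−1.79 to −1.41). The processed pseudogene Gm6977 fell by 3.17 (SE 0.43, adjusted p = 0.0265) with opposite pairs, −3.38 in blood and 0.43 after stroke, and it shares 3′ sequence with other genes.

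Further genes of the same class had sizeable values that did not pass. G0s2, an inhibitor of lipolysis, was at 1.15 ± 0.21 (adjusted p = 0.0710), and in blood its ratio was 1.41 (1.34 to 1.49), with UMIs in 70.8% of aged and 39.6% of young mature cells. Camp, the cathelicidin of the specific granules, was at 2.04 (adjusted p = 0.264), with its UMIs in few cells: 10 cells held 52.9% and 61.3% of those of young and aged mice after stroke, and 1 aged blood cell held 93.0% of 187 UMIs against none in young blood. Cybb, a subunit of the NADPH oxidase, was at 0.71. The antiviral genes Ifit1, Oas2 and Ifi27l2a were at −1.59, −1.69 and −1.15 (adjusted p = 0.0710 each), and Oasl2 was at −1.25. Of the 20 maturation and release receptors none passed, and their median was −0.06 (adjusted p = 0.393, camera). Among them Cxcr2 was at −0.02, Cxcr4, the receptor for marrow retention, at −0.24, Ly6g at −0.52 and the G-CSF receptor gene Csf3r at −0.57. The gelatinase gene Mmp9 was at 0.35. Among single ratios after stroke, without a p-value, Thbs1, which encodes thrombospondin, was at 3.61 (3.07 to 4.34, 264 aged and 24 young UMIs, in 53.2% and 9.14% of cells) and Stfa2, a stefin gene, at 2.70 (2.22 to 3.30).

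Of the gene lists, 35 interferon-stimulated genes had a median of −0.77 in aged mature cells, with none past the threshold over all genes and 17 lower when adjusted over the list alone (adjusted p = 7.57e-11, camera). The 10 specific granule genes had a median of 0.55, with 1 higher and, adjusted over the list alone, 3 higher (adjusted p = 4.74e-05). The 9 azurophil granule genes (0.50, adjusted p = 0.0280), the 10 genes of the oxidative burst (0.24, adjusted p = 0.0155), the 36 ribosomal protein genes (0.24, adjusted p = 2.92e-08) and the 30 genes of oxidative phosphorylation (0.17, adjusted p = 2.55e-04) also lay higher as lists. Adjusted over the list alone, 2 genes of the oxidative burst and none of the other 3 lists were higher. Genes with a pseudogene copy had a median of 0.15 in this fit (random sets −0.06 to 0.02), the 8 genes of oxidative phosphorylation without shared 3′ sequence had 0.09, and too few such ribosomal genes remained, so the rises of these 2 lists are uncertain. The inflammatory list (27 genes, −0.19, adjusted p = 0.0308) and the glucocorticoid-responsive list (15 genes, −0.12, adjusted p = 0.0139) lay lower, with 1 and 0 genes past the threshold when adjusted over the list alone. Each of these list calls was lost in this class, at adjusted p = 0.746 with an estimated correlation, a test with too few residual degrees of freedom to decide them. In blood, different clusters held most of the class by age, namely cluster 2 with 904 of the young cells and clusters 0 and 1 with 1552 and 1146 of the aged cells. The interferon-rich cluster 4 had 254 of 1436 young and 270 of 3062 aged cells, a smaller share of the aged class. After stroke the class was made of cluster 3 (129 young, 117 aged cells), whose mean log2 fold against the other neutrophil clusters was higher for immature (−0.05) than for mature markers (−0.35), and cluster 27 (57 and 24 cells; −3.01 and 1.10), so the less mature cluster held more of the aged class. Steap4 and Gm6977 are among the leading genes of blood cluster 2 and G0s2 among those of blood cluster 0. Their blood values may therefore follow the make-up of blood, which was not tested within clusters. The count of 3 genes became 0 with doublets kept (330 at unadjusted p below 0.05), 0 at a resolution of 0.5 (410 unadjusted), 26 with DESeq2 size factors, 1 with the DESeq2 test and 64 without a filter on low counts.

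When immature and mature cells of all 6 libraries were joined, 5 of 10310 genes passed, each lower in aged mice. Oasl2 fell by 1.42 on the log2 scale (SE 0.15, adjusted p = 0.0220) and Ifi27l2a fell by 1.16 (SE 0.13, adjusted p = 0.0220), both lower in each of the 3 contexts. In the immature cells of each marrow library, 10 cells held 49.3% to 83.3% of the Ifi27l2a UMIs. Ifit1 fell by 1.63 (SE 0.21), Steap4 fell by 1.73 (SE 0.22) and the immediate early gene Egr1 fell by 1.91 (SE 0.25), each at adjusted p = 0.0376. Egr1 was lower in steady-state marrow (−1.92) and blood (−1.85) and not after stroke (0.14), and Steap4 had no difference in steady-state marrow (−0.01), where it was hardly detected. Socs3, an inhibitor of cytokine signalling, was at −0.92 (adjusted p = 0.0723), Isg15 at −0.93 and Rtp4 at −0.98 (adjusted p = 0.0904 each), and Hcar2, a receptor for hydroxybutyrate, at −1.01 (adjusted p = 0.0950), none past the threshold. Jun was at −0.52, Prtn3 at 0.47, Ncf4 at 0.27 and Ppia at 0.54, likewise not past it.

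As a list, 35 interferon-stimulated genes had a median of −0.66 in the joined class, with 3 lower and, adjusted over the list alone, 21 lower (adjusted p = 3.52e-23, camera, and adjusted p = 0.551 with an estimated correlation). All 30 genes of oxidative phosphorylation had values above 0, with a median of 0.17 and none past the threshold on either adjustment (adjusted p = 3.31e-08, and 0.593 with an estimated correlation). The 8 without shared 3′ sequence had a median of 0.14, and genes with a pseudogene copy one of 0.13 (random sets −0.01 to 0.05), so this rise is uncertain too. The 23 immediate early and dissociation stress genes (median −0.05, 1 lower, 3 lower adjusted over the list alone, adjusted p = 0.00116) and the 22 maturation and release receptors (−0.09, none past the threshold, adjusted p = 0.0225) lay lower. The former list also marks stress from cell dissociation, which cannot be told apart here. The 10 azurophil granule genes (0.30, adjusted p = 0.00634) and the 10 genes of the oxidative burst (0.18, adjusted p = 0.00755) lay higher, with none past the threshold on either adjustment. These 4 list calls were lost at adjusted p = 0.551 with an estimated correlation. Cxcr2 was at −0.06 and Cxcr4 at −0.24. The class was made of immature cells in steady-state marrow and mature cells in blood. Steap4, Egr1 and Hcar2 are among the leading genes of blood cluster 2 (904 young and 94 aged cells). Their blood values may therefore follow the make-up of blood, which was not tested within clusters. Oasl2 and Ifi27l2a share 3′ sequence and were not in the fit without such genes, where the other 3 stayed past the threshold. Without the interferon-rich blood cluster the count was 0 (634 at unadjusted p below 0.05, edgeR), with all 5 genes still lower: Oasl2 was at −1.39 (SE 0.16, adjusted p = 0.0541), Ifi27l2a at −1.08 (SE 0.14), Steap4 at −1.78 (SE 0.22) and Egr1 at −1.89 (SE 0.26) (adjusted p = 0.0683 each), and Ifit1 at −1.35 (SE 0.36, adjusted p = 0.643). Without young blood or without aged blood 6 genes passed and 1 of the 5 stayed past the threshold. The count rose to 84 without the young stroke library, 33 without the aged one, 14 and 11 without the aged and young libraries of steady-state marrow.

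The third question was the effect of age in immature neutrophils of the marrow, where 10 genes were higher and 2 lower in aged mice among 8747. Stfa1, which encodes a stefin that inhibits cysteine proteases, rose by 0.99 ± 0.13 (adjusted p = 6.59e-06) and Wfdc17, a whey acidic protein-like secreted factor, by 1.03 ± 0.17 (adjusted p = 5.21e-04). Ldhc, a lactate dehydrogenase, rose by 1.29 ± 0.22 (adjusted p = 5.64e-04), mainly after stroke, where its ratio was 2.14 (1.78 to 2.65, 367 and 52 UMIs) against 0.30 (−0.07 to 0.71, 128 and 100 UMIs) at steady state. Also higher were Mrgpra2b (0.81, adjusted p = 5.65e-05), a G protein-coupled receptor gene, the membrane protein gene Ifitm2 (0.75, adjusted p = 6.29e-05), the ATP synthase gene Atp5l (0.94, adjusted p = 0.00261), Trim37 (1.38, adjusted p = 0.00303) and the NAD-consuming ectoenzyme gene Cd38 (1.30, adjusted p = 0.0368). Trim37 and Cd38 lay below the mean of 20 CPM that the naming rule asks for, and were chosen after their values had been seen. Ifi27l2a fell by 1.03 (SE 0.19, adjusted p = 0.00200), with ratios of −1.09 and −0.89. Its UMIs sat in few cells. At steady state 10 cells held 49.3% of 209 young and 56.6% of 99 aged UMIs. After stroke 10 cells held 75.5% of 53 young and 83.3% of 42 aged UMIs. A few cells may therefore set its value, which was not tested. The globin gene Hbb-bs fell by 6.67 (SE 0.33), and haemoglobin transcripts made up 946 CPM of young and 4.55 CPM of aged immature cells at steady state. Olfm4, which marks a subset of neutrophils, did not pass (0.94, adjusted p = 0.163): its ratio was 2.28 after stroke (2.13 to 2.45, UMIs in 54 of 316 aged and 7 of 170 young cells) and −0.32 at steady state (−0.42 to −0.23).

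Of 26 alarmins and secreted neutrophil proteins, 3 rose in aged immature cells and 8 when adjusted over the list alone (median 0.09, adjusted p = 7.58e-08, camera). Of 29 interferon-stimulated genes, 1 fell and 5 when adjusted over the list alone (median −0.30, adjusted p = 6.86e-06, and 0.396 when only members with a mean of at least 20 CPM were used). The azurophil granule list (10 genes, 0.15, adjusted p = 0.00351), glycolysis (22, 0.05, adjusted p = 0.0249) and oxidative phosphorylation (30, 0.07, adjusted p = 0.0169) lay higher with no gene past the threshold. The 20 maturation and release receptors lay lower with none past it (−0.08, adjusted p = 0.0324). All of these list calls were lost in this class, at adjusted p = 0.908 with an estimated correlation. Genes with a pseudogene copy had a median of 0.05 (random sets −0.01 to 0.04), near those of glycolysis and oxidative phosphorylation. Cxcr2 was at 0.25, Cxcr4 at −0.34, Lrg1 at 0.36, Prtn3 at 0.38, Gapdh at 0.32 and the antiviral gene Rsad2 at −1.29, none past the threshold. Stfa1, Mrgpra2b, Ifitm2, Atp5l, Ifi27l2a and Hbb-bs share 3′ sequence with other genes and are uncertain. Without all such genes none passed (0 of 4969, 225 at unadjusted p below 0.05, edgeR), while the 4 called genes still measured kept their values with adjusted p above the threshold: Wfdc17 was at 1.05 (SE 0.21), Trim37 at 1.39 (SE 0.28) and Cd38 at 1.32 (SE 0.27) (adjusted p = 0.461 each), and Ldhc at 1.29 (SE 0.30, adjusted p = 0.859). None passed either with the DESeq2 test (34 unadjusted), and 1 gene passed with doublets kept or with cells thinned to equal depth.

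In dividing pre-neutrophils, 34 genes were higher and 14 lower in aged mice among 8825. The stefin genes Cstdc4 (1.42 ± 0.17, adjusted p = 7.58e-13) and Stfa2l1 (1.05 ± 0.13, adjusted p = 6.51e-12) rose, as did the kinase gene Pim1 (0.87, adjusted p = 1.49e-06), Il1r2 (0.67, adjusted p = 6.32e-04) and Cxcr2 (0.55 ± 0.12, adjusted p = 0.00134), a receptor that draws neutrophils out of the marrow. Cxcr4 fell by 0.48 (SE 0.12, adjusted p = 0.0161). Of the 18 maturation and release receptors these were the only 2 past the threshold, also when adjusted over the list alone (median 0.06, adjusted p = 0.845). Olfm4 rose by 1.32 ± 0.11 (adjusted p = 3.16e-29), nearly all of it after stroke, where the ratio was 4.22 (3.75 to 4.96, 715 and 25 UMIs) against 0.16 (0.02 to 0.29) at steady state. Its SE and p-value lean on the spread pooled over genes and do not reflect how far these ratios lie apart. Ifi27l2a fell by 1.6 (SE 0.29, adjusted p = 2.79e-05), from low levels. It was at 15.2 CPM in young and 7.09 CPM in aged cells at steady state, and at 25.1 and 5.01 CPM after stroke. The antigen presentation genes H2-Eb1 and H2-Ab1 fell by 1.55 and 1.18 in the fit with opposite pairs, 1.22 and 0.96 at steady state and −2.42 and −2.60 after stroke. The histone gene Hist2h2bb fell by 0.90, the metallothionein gene Mt1 by 0.82, St3gal5 by 0.46, the lysozyme gene Lyz2 by 0.37, and the mitochondrial transcripts mt-Nd5, mt-Rnr1 and mt-Rnr2 fell by 0.44, 0.42 and 0.40.

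Of 24 alarmins and secreted proteins, 8 rose in aged dividing cells, among them Ifitm1 (0.69), Ifitm6 (0.48) and Ifitm2 (0.47), and 9 rose and 2 fell when adjusted over the list alone (median 0.12, adjusted p = 3.37e-09, camera). Of 36 ribosomal protein genes 2 rose, Rpl27a (0.55) and Rps6 (0.51), and 3 when adjusted over the list alone (median 0.12, adjusted p = 5.72e-12). Rpl15 (0.70), Atp5l (0.86), Mrgpra2b (0.63), the ferritin gene Ftl1 (0.47) and Ms4a3 (0.39) also rose. The 8 mitochondrially encoded transcripts lay lower (median −0.16, 1 lower, 2 lower adjusted over the list alone, adjusted p = 0.00879), and the 14 chemokine receptors higher (0.19, 1 higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.0359). Each of these list calls was lost in this class, at adjusted p = 0.626 with an estimated correlation. Genes with a pseudogene copy had a median of 0.06 (random sets −0.01 to 0.03), so the rise of the ribosomal list is uncertain. The 20 interferon-stimulated genes (−0.01, adjusted p = 0.137) and the 7 class II genes (−0.50, adjusted p = 0.299) were not past the threshold as lists. Only 59 young and 89 aged dividing cells came from marrow after stroke. The count of 48 genes was 0 with the DESeq2 test (35 at unadjusted p below 0.05), 2 with a minimum of 1000 UMIs or thinned cells, 21 with DESeq2 size factors and 19 without genes that share sequence, a group that includes Stfa2l1, Cxcr2, Ifi27l2a, Rpl15, Atp5l, Rps6 and Ftl1.

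**Figure D2:**
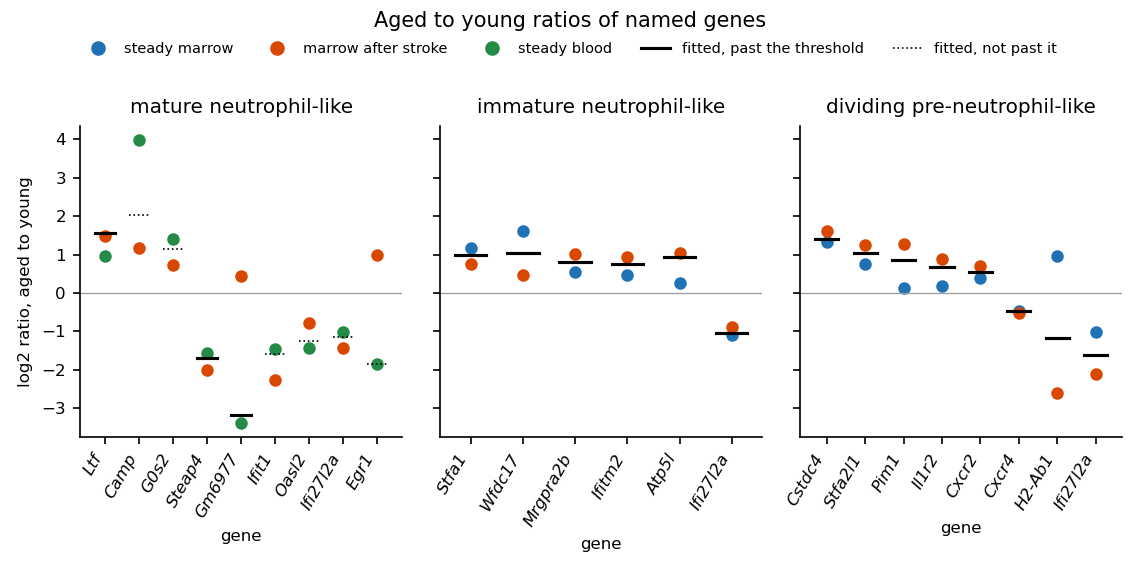
Log2 ratio of aged to young (vertical axis) for named genes (horizontal axis) in mature, immature and dividing neutrophil-like cells, with 1 point per pair of libraries and a line at the fitted value, solid where the gene passed the threshold and dotted where it did not. Ifi27l2a lies below 0 in each pair of all 3 classes, while H2-Ab1 and Gm6977 have points on both sides of 0.

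Because genes of the interferon list recurred, the same list was described in each cell class and context, as medians of aged to young ratios without p-values. In blood the median was −0.88 in mature neutrophils, with 36 of 38 genes lower and the central 95% of random lists between −0.11 and 0.11. Without the interferon-rich cluster it was −0.80, with 33 of 34 genes lower. It was −1.01 in non-classical monocytes, −0.54 in classical monocytes, −0.78 in B lineage cells and −0.49 in NK cells of blood, each below its random range. In steady-state marrow the median was −0.30 in immature neutrophils, −0.26 in classical monocytes, −0.26 in erythroid cells, −0.22 in granulocyte-monocyte progenitors and −0.17 in dendritic cells, each below the range, and 0.00 in stem and progenitor cells and −0.04 in dividing pre-neutrophils, within it, as were basophils and mast cells (−0.11) and megakaryocytes (−0.04). After stroke immature neutrophils (−0.38), stem and progenitor cells (−0.20) and classical monocytes (−0.18) lay below the range, mature neutrophils (−0.19), dividing pre-neutrophils (−0.30), dendritic cells (−0.19), granulocyte-monocyte progenitors (−0.15), NK cells (−0.07), erythroid cells (−0.06) and B lineage cells (0.15) within it, and T cells (0.34) above it.

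**Figure D3:**
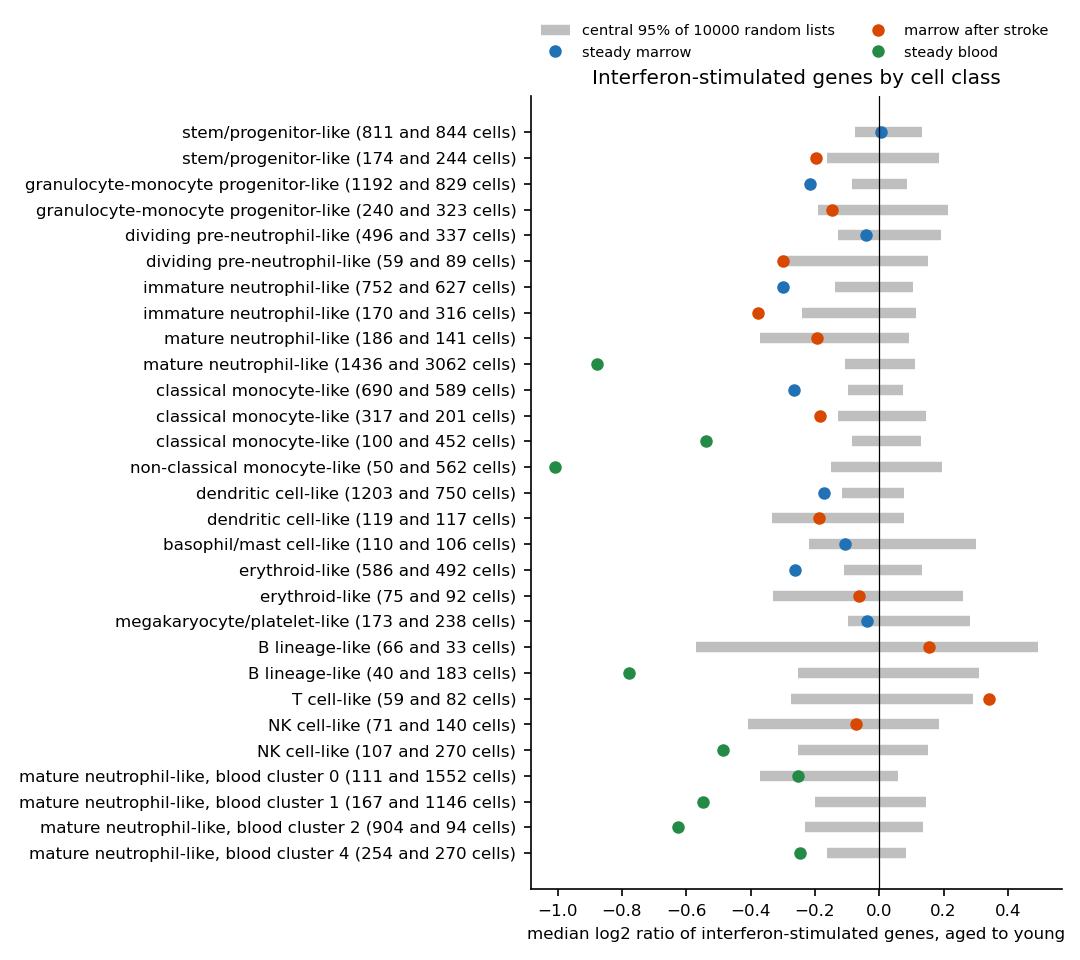
Median log2 ratio of aged to young over interferon-stimulated genes (horizontal axis) for each cell class and context (vertical axis, with the numbers of young and aged cells), where points are medians and grey bars the central 95% of 10000 random lists of matched expression. Points of blood reach down to −1.01 in non-classical monocyte-like cells and −0.88 in mature neutrophil-like cells, and that of blood cluster 0 lies within its bar.

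The fourth question was how marrow neutrophils 24 h after stroke differed from those at steady state. The stroke and steady-state libraries also differed in ways the design cannot separate from stroke: in the limits used before deposit, in depth, and in genes with near-identical copies. Over all kept cells, processed pseudogenes made up 5425 (young) and 5694 (aged) CPM in steady-state marrow, 15048 and 16234 CPM after stroke, and 10551 and 9620 CPM in blood. The ferritin gene Ftl1, with 77.1% of its 3′ words in other genes, was at 56.0 and 87.4 CPM in steady-state marrow, 1089 and 1089 CPM after stroke and 3676 and 3279 CPM in blood. Ppia moved from 230 and 342 CPM to 1598 and 1914 CPM, and Atp5l from 14.4 and 17.0 CPM to 120 and 209 CPM. B2m, in contrast, was at 1162 and 1133 CPM at steady state and 703 and 692 CPM after stroke. Values of genes with copies are therefore uncertain below, and counts over all genes are also given without them.

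**Figure D4:**
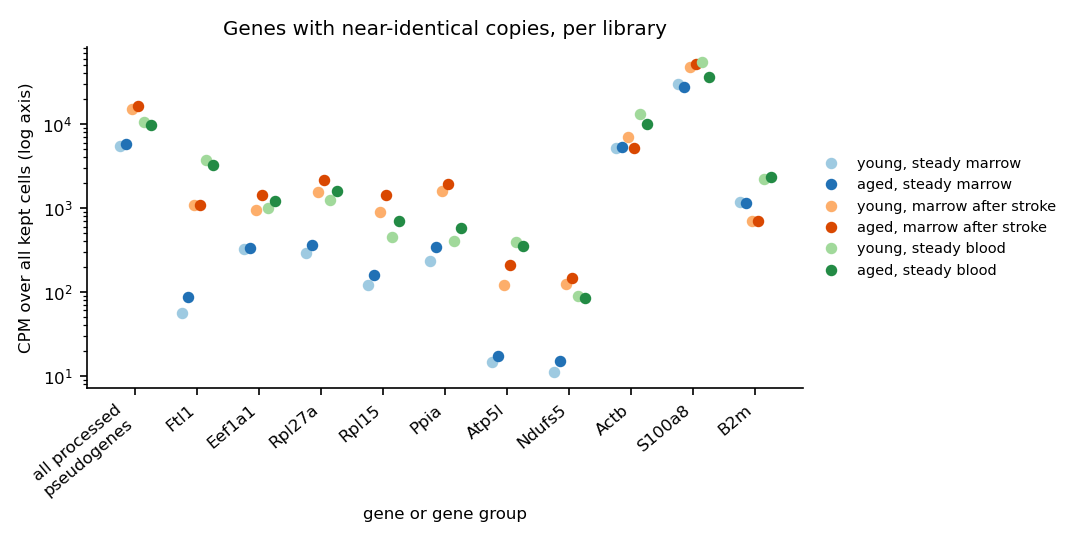
CPM over all kept cells (vertical axis, log scale) of genes with near-identical copies and of comparison genes (horizontal axis), with 1 point per library. Processed pseudogenes reach 15048 and 16234 CPM in the stroke libraries against 5425 and 5694 CPM in steady-state marrow.

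In immature neutrophils 1127 genes were higher and 890 lower after stroke among 8747, and 1893 of them had the same sign in young and aged mice. Lipg rose by 5.51 ± 0.27 (adjusted p = 4.45e-21), with ratios of 3.67 in young (3.19 to 5.34, 112 and 9 UMIs) and 5.35 in aged mice (4.99 to 8.24, 339 and 4 UMIs). Asprv1, a retroviral-like aspartic protease, rose by 2.76 ± 0.13 (adjusted p = 1.11e-21), Il1r2 by 1.62 ± 0.15 (adjusted p = 4.81e-12), and the chemokine receptor Ccr1 by 1.17 ± 0.11. Genes of the azurophil granules, which are made early in neutrophil development, fell: Mpo fell by 2.53 (SE 0.15, adjusted p = 7.29e-18), and the protease genes Elane by 2.51 (SE 0.17) and Ctsg by 1.37 (SE 0.19). The proliferation genes Top2a and Mki67 fell by 1.77 and 1.64. The inflammatory cytokine gene Il1b fell by 2.73 (SE 0.27, adjusted p = 5.10e-11), and Irf8, a transcription factor of the monocyte fate, fell by 2.90. Csf1r (−2.27), the beta-glucan receptor gene Clec7a (−2.20), the chemokine gene Ccl6 (−2.10), Tnfsf13b, which encodes the B cell survival factor BAFF (−1.94), and the short-chain fatty acid receptor gene Ffar2 (−1.47) fell too.

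By list, 21 of 26 alarmins and secreted proteins rose and 2 fell after stroke in immature cells (22 and 3 adjusted over the list alone, median 0.78, adjusted p = 1.15e-15, camera), with Ifitm1 at 2.31 and Ifitm2 at 1.80. Of 25 cell cycle genes 15 fell and 1, Hmgb2 (1.25), rose (18 and 1 adjusted over the list alone, median −1.17, adjusted p = 6.12e-08). Hmgb2 shares 28.3% of its 3′ words with other genes, so its rise is uncertain. Of 10 azurophil granule genes 6 fell and 2 rose, the same adjusted over the list alone (−0.73, adjusted p = 6.08e-04), and of 10 genes of gelatinase granules and secretory vesicles 6 rose and 1 fell on both adjustments (0.48, adjusted p = 0.00430), among them Slpi (0.90), Fpr1 (0.72) and Mmp9 (0.56). Glucocorticoid-responsive genes (12, 5 higher, 6 adjusted over the list alone, 0.54, adjusted p = 0.00156), with Fkbp5 at 1.0 and Tsc22d3 at 0.68, and chemokine receptors (14, 6 higher, 8 adjusted over the list alone, 0.35, adjusted p = 0.00131) lay higher as lists. Glycolysis (22, 10 higher) and oxidative phosphorylation (30, 17 higher) each had a median of 0.36 (adjusted p = 9.19e-07 each), with 12 and 18 higher and 1 and 2 lower when adjusted over the list alone, and with Gapdh (1.5), Eno1 (1.51), Pgk1 (2.81), Cycs (1.74) and Cox7c (1.04) among them. Of 29 interferon-stimulated genes 9 fell, including Ifi27l2a (−1.06), and 3 rose (12 and 3 adjusted over the list alone, −0.43, adjusted p = 0.0256). All of these calls were lost at adjusted p = 0.659 with an estimated correlation, and those of the cell cycle and interferon lists also among members with a mean of at least 20 CPM (adjusted p = 0.0546 and 0.389).

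Of the 20 maturation and release receptors 6 rose and 4 fell in immature cells after stroke (6 and 5 adjusted over the list alone, median 0.05, below 0 under library totals, adjusted p = 0.744). Cd14 (1.73), Cd177 (0.79), the selectin ligand gene Selplg (0.79), Cd47 (0.54) and Cxcr2 (0.49, with ratios of −0.18 in young and 0.49 in aged mice) rose, and Ly6g (−1.06) and the integrin gene Itgam (−0.40) fell. Other genes that rose were Alox5ap (1.37), which serves leukotriene synthesis, the urokinase receptor gene Plaur (1.19), Pirb (1.14), the transcription factor genes Cebpb (1.12) and Jund (1.06), the chaperone gene Hspa8 (1.27) and the haptoglobin gene Hp (0.94), and Fcnb (−1.17) and Lyz2 (−0.92) fell. Hspa8, Lyz2 and Pirb share 71.4%, 37.0% and 18.5% of their 3′ words with other genes, so their values are uncertain. Markers of other cells moved as well: Hbb-bs was at −5.47 (3 of 4 haemoglobin genes fell) and the immunoglobulin gene Igkc at −1.60 (4 of 6 B cell genes fell), and 3 of 9 monocyte genes fell. Genes with copies rose strongly, among them Ftl1 (3.75), Atp5l (3.73), Ndufs5 (3.72), Sec61g (3.54), Ppia (3.16), Rpl15 (2.98), Rpl27a (2.70) and Rps6 (2.02), and the ribosomal RNA-related transcripts Mir6236 (3.65) and AY036118 (3.57) rose too. Without genes that share sequence, 425 rose and 298 fell among 4969, and the medians of alarmins (0.80), azurophil granule (−1.33), gelatinase granule (0.68) and glucocorticoid-responsive genes (0.44) kept their signs. Of the lists with many copies, 2 of 9 glycolysis genes (0.37) and 4 of 8 of oxidative phosphorylation (0.34) then rose, 2 of 6 cell cycle genes fell (−1.01), and of 17 interferon-stimulated genes 2 fell and 1 rose (−0.38).

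Scaling to library totals in place of TMM lowered the median of all genes after stroke to −0.34 in immature and −0.25 in dividing cells. The lists of alarmins, glycolysis and oxidative phosphorylation kept their signs under it (glycolysis 0.04 and 0.17, oxidative phosphorylation 0.04 and 0.02), and the ribosomal list of immature cells flipped from 0.11 to −0.21. The count of 2017 genes was 427 with the DESeq2 test (350 higher, 77 lower) and 431 with cells thinned to equal depth (290 higher, 141 lower), so the share of higher calls depended on the tool. Clusters 4 and 7 held the immature cells at steady state and clusters 2 and 4 of a separate clustering held them after stroke. Mmp9, Retnlg and Ly6g were among the leading genes of steady-state cluster 4. After stroke 186 young and 141 aged cells were named mature, while no steady-state cells were. The line between immature and mature cells may therefore lie differently in these contexts. How far the immature values depend on it was not tested.

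In dividing pre-neutrophils 1400 genes were higher and 1108 lower after stroke among 8825, and 2388 of them had the same sign in both ages. The differences between libraries named above apply here as well. Lipg rose by 5.09 ± 0.22 (adjusted p = 1.63e-108), Wfdc17 by 2.78 ± 0.14 (adjusted p = 1.96e-80), Il1r2 by 2.47 ± 0.14 (adjusted p = 1.68e-66) and the apolipoprotein gene Apoe by 3.76 ± 0.17 (adjusted p = 5.10e-105). The protease genes Prtn3 (1.81) and Elane (1.03) rose and Mpo fell by 0.97, where in immature cells both Mpo and Elane fell. An unnamed steady-state cluster led by Elane, Prtn3 and Mpo among neutrophil clusters (354 young and 187 aged cells) was outside the class. So was an unnamed cluster after stroke with Elane among its leading genes (20 and 81 cells). How far these values depend on that naming was not tested. Class II presentation genes rose, with higher ratios in young than in aged mice, a difference that was not tested: the ratio of the invariant chain gene Cd74 was 4.29 (3.95 to 5.03, 328 and 33 UMIs) in young and 1.01 (0.67 to 1.41, 161 and 99 UMIs) in aged cells. H2-Eb1 (3.62) and H2-Aa (2.81) rose with ratios of 4.62 and 4.47 in young and 0.99 and 0.44 in aged mice, and H2-Ab1 (2.17) went both ways (3.31 and −0.24). Of 9 genes that mark monocytes 5 rose and 2 fell on both adjustments (median 0.82, adjusted p = 0.124), and doublets remain in the stroke libraries. Olfm4 fell by 0.88 in the fit, with ratios of −3.99 in young and 0.07 in aged mice. The receptor genes Ccr2 (2.23) and Ccr1 (1.51) rose, and Tnfsf13b (−1.92), Cstdc4 (−1.69), Ffar2 (−1.26), Ly6g (−1.25), Lyz2 (−1.19) and the stem cell factor receptor gene Kit (−1.18) fell.

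Of 24 alarmins and secreted proteins 20 rose and 3 fell in dividing cells on both adjustments, over all genes and adjusted over the list alone (median 0.86, adjusted p = 1.06e-10, camera), with Stfa1 at 1.56, Ifitm2 at 1.59 and S100a6 at 1.24. Of 9 glucocorticoid-responsive genes 7 rose, and 8 adjusted over the list alone (0.62, adjusted p = 1.10e-04), with Mt1 at 1.78, the phosphatase gene Dusp1 at 1.38 and Fkbp5 at 0.65, and of 7 class II genes 5 rose on both adjustments (2.26, adjusted p = 0.00169). Of 36 ribosomal protein genes 33 rose and 1 fell (33 and 2 adjusted over the list alone, 1.0, adjusted p = 4.78e-34), with Rpl27a at 3.68, Rpl35 at 2.77, Rps6 at 2.57 and Rpl13 at 1.84, all of which have copies. Oxidative phosphorylation (30, 18 higher and 1 lower on both adjustments, 0.25, adjusted p = 1.94e-08) and glycolysis (22, 10 higher and 1 lower on both adjustments, 0.40, adjusted p = 8.41e-04) lay higher, with Cycs at 2.37, Cox7c at 1.27, Pgk1 at 3.17 and Gapdh at 1.92, all of which share 3′ sequence. Without such genes 1 of 9 glycolysis genes rose, with a median of 0.07, and 5 of 8 of oxidative phosphorylation (0.30). Immediate early and dissociation stress genes (17, 9 higher and 2 lower, 9 and 3 adjusted over the list alone, 0.55, adjusted p = 0.0252), with Jun at 1.93 and Hspa8 at 1.48, lay higher too, and Hspa8 shares 71.4% of its 3′ words with other genes. Stress from cell dissociation cannot be told apart from stroke in this list. Each of these list calls was lost in this class, at adjusted p = 0.822 with an estimated correlation.

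Of 25 cell cycle genes 6 rose and 3 fell in dividing cells (6 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.646, below 0 under library totals), with Hmgb2 (1.39) and Stmn1 (1.21) higher and Aspm (−1.23), Cenpf (−0.96) and Mki67 (−0.60) lower. Hmgb2 and Stmn1 share 28.3% and 29.6% of their 3′ words with other genes, so their rises are uncertain. Aspm, Cenpf and Mki67 share 0.55%, 5.65% and 5.27%. Of the 18 maturation and release receptors 5 rose and 7 fell (5 and 8 adjusted over the list alone, −0.22, adjusted p = 0.124), with Selplg (0.78), Cd177 (0.62) and Cxcr2 (0.46) higher and Vcam1 (−0.96) and Itgam (−0.87) lower. Serpinb1a (1.0), Cebpb (0.92) and Hp (0.85) rose. Histone and copy genes rose strongly, among them Hist1h2ai (5.60), Hist1h3b (5.14), Rpl6l (5.0), Hist1h2ab (4.92), Tpt1-ps3 (4.46) and Ftl1 (3.90), whose values are uncertain. The 59 young and 89 aged dividing cells after stroke lay in 1 cluster with a median of 30790 UMIs, against 8508 UMIs in cluster 6 of steady-state marrow, the larger of its 2 clusters. Without genes that share sequence, 560 rose and 508 fell, and 15 of 16 alarmins (0.94), 6 of 6 glucocorticoid-responsive genes (1.04), 3 of 4 class II genes (2.60) and 8 of 14 immediate early and dissociation stress genes (0.63) rose. With doublets kept Cstdc4 was at 3.35, and with cells thinned to equal depth Fkbp5 was at −0.66, both of the opposite sign. The count of 2508 genes was 607 with the DESeq2 test (513 higher, 94 lower) and 395 with cells thinned to equal depth (304 higher, 91 lower).

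**Figure D5:**
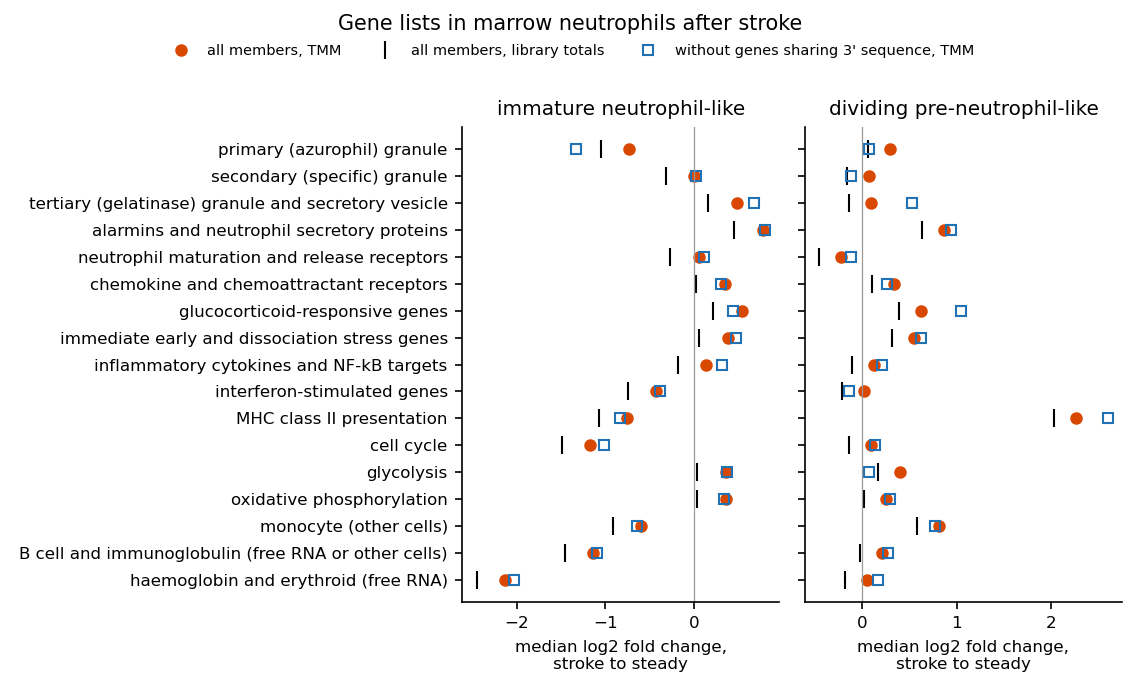
Median log2 fold change of stroke to steady state (horizontal axis) for gene lists (vertical axis) in immature and dividing neutrophil-like cells, with filled points for all members under TMM scaling, ticks for the same under library totals and open squares for members without shared 3′ sequence. The alarmin list lies at 0.78 and 0.86, and the class II list at 2.26 in dividing cells.

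In immature and mature neutrophils joined, 1047 genes were higher and 525 lower after stroke among 10310. This class was made of immature cells alone in steady-state marrow and of immature and mature cells after stroke, so the contrast also sets stages against each other, besides the libraries. The count of 1572 genes was 864 with the DESeq2 test (666 higher, 198 lower), 485 without the young and 678 without the aged library of steady-state marrow, and 957 without the aged stroke library.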

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

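The tests of the make-up of the blood class, of other cell classes and of the cell limits and of calls without shared sequence, the counts of other splits and the test of Ltf in few cells were chosen only after the result had been seen.

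The direction of age in class II presentation genes differed between contexts in dividing pre-neutrophil-like cells, with a median log2 ratio of aged to young of 0.86 in steady-state marrow and −1.48 after stroke, and the difference was not tested. Only 59 young dividing cells came from marrow after stroke. Haemoglobin and erythroid genes differed likewise in classical monocyte-like cells, with a median of 3.79 in blood, −0.85 in steady-state marrow and −0.71 after stroke, also not tested.

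Interferon-stimulated genes were lower in aged than in young mature neutrophils of blood, where the clusters that hold the class differ by age, and in immature neutrophils of marrow, while mature cells after stroke and dividing cells in both contexts lay within the range of random lists. The list calls of the mature, joined and immature classes were lost with an estimated correlation (adjusted p = 0.746, 0.551 and 0.908), a test with too few residual degrees of freedom to decide them. A different make-up as the whole cause is argued against, since the list median lay below the range of random lists within 3 of the 4 blood clusters, and in the other, cluster 0, it was within the range. Within clusters 0, 1, 2 and 4 the medians were −0.25, −0.55, −0.62 and −0.25, each smaller in size than the −0.88 of the class. Make-up therefore stays a candidate source of part of the difference. A difference that other cell classes share is a candidate explanation, because 52.6% of the pairs of libraries in other classes (10 of 19) also had a median below the range, although these classes come from the same libraries and are not independent. An effect of age on the animals and a difference between single libraries or animals cannot be separated here, and age stays open as untested. With 10 splits of the 6 libraries a share under 0.05 cannot be reached: the real split gave 5 genes in the joined class and the highest of the others 9, and 3 of the 10 gave at least as many as the real one. The splits with 9 put both libraries of each marrow context on the same side, so that with the context term they measure young against aged blood alone. There age cannot be told apart from a difference between single libraries. The blood libraries alone thus gave more genes than the difference averaged over contexts. The 4 splits that set young against aged or the reverse within each context gave 5 (the real one), 1, 0 and 0 genes, too few splits for such a share either.

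Marrow neutrophils after stroke differed from those at steady state in 2017 genes of the immature class. The line between immature and mature cells may lie differently in the contexts compared, and its part in these calls was not tested. Equal limits in every library left 2038 genes, so stroke cells beyond the steady-state limits did not carry the calls. These limits removed hardly any cells: 169 of 170 young and 314 of 316 aged immature cells stayed after stroke, and all at steady state. Cells cut before deposit cannot be restored, so whether different limits before deposit matter cannot be decided this way. Reads shared with pseudogenes may account for part of the rises: genes with a pseudogene copy had a median of 0.30 in immature cells (233 genes, random sets 0.00 to 0.13) and 0.55 in dividing cells (243 genes, random sets 0.03 to 0.16). Shared 3′ sequence as the whole cause is argued against, since 723 of the 4969 genes without it passed, 425 higher and 298 lower, where it allows none beyond false calls. Their share of 14.6% against 23.1% of all genes was under the bound set beforehand for excluding it, which compared sizes of the shares and left a part for it open, so it stays a candidate source of part of the calls. A difference between library batches cannot be told apart from stroke, since all stroke libraries stand on one side: 74.0% of the called genes measured in stem and progenitor cells moved the same way there in young and in aged mice, and an effect of stroke on the whole marrow, untested, would do the same.

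Ltf was higher in aged mature neutrophil-like cells. A few cells rich in granule transcripts are a candidate source, because in both stroke libraries 10 cells held at least 64.1% of its UMIs, while in blood too few cells had a UMI for this test. The make-up of the class after stroke differed by age as well, and this was not tested: the less mature cluster 3 held 129 young and 117 aged cells and cluster 27 held 57 and 24. Without the 10 richest cells per library the fold change was 1.18 (SE 0.30, adjusted p = 0.185) against 1.55 (SE 0.24, adjusted p = 0.0442), so the call ended with a smaller value and a larger error, and whether the remaining cells differ with age stays open.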

How the results depend on the processing

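The settings without granule-rich cells, without the interferon-rich blood cluster, with equal cell limits and without genes that share 3′ sequence were chosen only after the data had been seen. No analysis paired by replicate number was possible, because each group has 1 library and the groups share only 1 replicate number. The context term of the main age fits does set young beside aged within each context.

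The age count in mature cells (3 genes) was 26 with DESeq2 size factors, 1 with the DESeq2 test (75 at unadjusted p below 0.05), 64 with no filter on low counts, 0 with doublets kept (330 unadjusted), 9 with at least 1000 UMIs, 0 at resolution 0.5 (410 unadjusted), 11 with thinned cells, 14 without 10 granule-rich cells per library, 11 without genes that share sequence, 0 with no context block (6 unadjusted) and 5 when all post-mitotic cells were joined. In the joined class (5 genes) it was 96 with no filter, 3 with doublets kept, 21 with thinned cells, 0 without the interferon-rich cluster (634 unadjusted), 3 without genes that share sequence and 0 with no context block (8 unadjusted). Leaving out 1 library gave 6 genes (without either blood library, with 1 of the 5 kept) to 84 (without the young stroke library), with 11 without young and 14 without aged steady-state marrow and 33 without the aged stroke library. In immature cells (12 genes) it was 0 with the DESeq2 test (34 unadjusted), 22 with no filter, 1 with doublets kept, 23 with at least 1000 UMIs, 28 at resolution 0.5 and at 2, 1 with thinned cells and 0 without genes that share sequence (225 unadjusted). In dividing cells (48 genes) it was 21 with DESeq2 size factors, 0 with the DESeq2 test (35 unadjusted), 2 with at least 1000 UMIs, 12 at resolution 2, 2 with thinned cells and 19 without genes that share sequence.

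The stroke count in immature cells (2017 genes) was 427 with the DESeq2 test, 431 with thinned cells and 723 without genes that share sequence. In dividing cells (2508) it was 607, 395 and 1068 in the same order. In the joined class (1572) it was 864 with the DESeq2 test and 716 without genes that share sequence, and leaving out 1 library gave 485 (without young steady-state marrow) to 1952 (without aged blood), with 678 without aged steady-state marrow and 957 without the aged stroke library. Of the 2017 genes all had the same direction with the DESeq2 test, and 1499 of the 1519 still measured had it with thinned cells. Of the 2508 genes of dividing cells, 1575 of the 1707 still measured had the same direction with thinned cells. The thinned setting and that without shared sequence test fewer genes, and the cause of the other differences was not tested.

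The gene lists past the threshold with age or stroke (9 in mature, 12 in joined, 10 in immature and 8 in dividing cells with age, 15 and 8 in immature and dividing cells with stroke) were 0 in each case with an estimated correlation. That test has only the 1 or 2 residual degrees of freedom of the fit, so hardly any list could pass it and the losses decide nothing. The test with the preset correlation treats the genes of a list as nearly independent. Its p-values can be too small where members move together, and they do not measure variation between animals. With members at a mean of at least 20 CPM the 10 of immature cells with age became 5. Cstdc4 in dividing cells after stroke reversed to 3.35 with doublets kept, and Fkbp5 to −0.66 with thinned cells. The cause was not tested.

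The share of all neutrophil stages was 15.8% and 15.6% (young and aged) in steady-state marrow, 18.4% and 20.7% after stroke and 72.9% in young blood. With doublets kept it was 12.3% and 12.7% in steady-state marrow and 79.8% in young blood. With at least 1000 UMIs it was 23.2% and 24.0% after stroke and 79.5% in young blood, and with at least 200 UMIs 68.8% in young blood. At resolution 0.5 it was 9.56% and 10.1% in steady-state marrow and 23.5% in aged marrow after stroke, and at resolution 2 it was 17.4% in young steady-state marrow and 75.8% in young blood.

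Named genes kept their direction and side of the threshold in 1804 of 2136 combinations of gene and setting, lost the threshold in 260, passed it newly in 70 and reversed in 2. Fits of 4 libraries have no residual degrees of freedom once 1 library is left out, so they give no such values. Dividing cells were too few at resolution 0.5 to be tested. The planned fit of mature cells over 6 libraries and the planned contrasts of stroke and of blood against marrow in mature cells were not run, as no mature class was found in steady-state marrow. Cell numbers limit the stroke libraries most, with 59 young dividing cells.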

Other observations

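The comparisons of age in stem and progenitor cells and in classical monocytes, the ratios of monocytes after stroke, those of Rsrp1 and the count of splits were chosen only after the data had been seen.

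In stem and progenitor-like cells of the marrow 157 genes were higher and 86 lower in aged mice among 12603, and 242 of these 243 had the same sign at steady state and after stroke (edgeR quasi-likelihood test). The stress-induced regulator gene Nupr1 rose by 4.26 ± 0.19 (adjusted p = 3.57e-07), the sulfotransferase gene Sult1a1 by 3.65 ± 0.21 (adjusted p = 4.36e-06), Clec1a by 3.73 and the transglutaminase gene Tgm2 by 3.34. The P-selectin gene Selp rose by 2.31 ± 0.19 (adjusted p = 4.87e-05), the aldehyde dehydrogenase gene Aldh1a1 by 2.65, and the megakaryocyte-associated gene Mmrn1 by 1.64. The lymphoid genes Ly6d (−2.43) and Dntt (−1.15) fell, as did Irf8 (−1.46), the chemokine gene Ccl3 (−1.95) and Ifi27l2a (−1.57). Of 18 glucocorticoid-responsive genes 4 rose, 5 when adjusted over the list alone, among them Mt2 (3.88), Mt1 (1.67) and Klf9 (0.75) (median 0.27, adjusted p = 7.76e-04, camera). Of 20 immediate early and dissociation stress genes 4 fell, Jun (−0.88), Zfp36 (−0.88), Btg2 (−1.07) and Dusp2 (−0.58), and 6 fell and 1 rose when adjusted over the list alone (−0.28, adjusted p = 4.68e-04). The 20 maturation and release receptors lay lower (−0.12, 1 lower, 3 lower adjusted over the list alone, adjusted p = 0.00637), and these list calls were lost at adjusted p = 0.833 with an estimated correlation. Nearly all cells of clusters 21 (20 young, 265 aged) and 28 (7 and 72) came from aged mice, and Nupr1, Sult1a1, Tgm2 and Mmrn1 are among their leading genes, while Dntt and Ly6d lead cluster 9 after stroke (107 young, 53 aged). The values of these genes may therefore follow the make-up of the class, which was not tested within clusters. The count of 243 genes was 46 with the DESeq2 test, 592 with no filter on low counts, 88 with at least 1000 UMIs, 571 and 154 at resolutions of 0.5 and 2, 127 with thinned cells and 156 without genes that share sequence.

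In classical monocyte-like cells 3 genes were higher and 1 lower with age among 11793. The complement genes C1qb (3.12 ± 0.23, adjusted p = 5.69e-04) and C1qa (3.27 ± 0.37, adjusted p = 0.0260) rose, with C1qb ratios of 2.45 in steady-state marrow, 3.10 after stroke and 0.91 in blood, and so did the eosinophil granule gene Prg2 (3.19 ± 0.29, adjusted p = 0.00569). C1qa had ratios of 2.83 and 2.42 and Prg2 of 3.02 and 1.20 in the marrow of both contexts, and neither had a UMI in blood monocytes of either age. Ifi27l2a fell by 0.89 (SE 0.12, adjusted p = 0.0387). Of 41 interferon-stimulated genes 1 fell, and 11 when adjusted over the list alone (median −0.40, adjusted p = 4.87e-16, camera, and adjusted p = 0.837 with an estimated correlation). Ctsl (0.67) and H2-Ab1 (0.89) did not pass. The count of 4 genes was 130 with no filter on low counts, 2 with at least 1000 UMIs and 8 without genes that share sequence. Without young steady-state marrow it was 1, without aged steady-state marrow 0 (373 at unadjusted p below 0.05, edgeR), without a stroke library 42 (young) and 41 (aged) and without a blood library 19 (young) and 94 (aged), and the 4 genes kept their direction each time. Cluster 5 held most aged (428) and few young (6) blood monocytes, and cluster 11 most young ones (94). With 10 splits a share under 0.05 cannot be reached: the real split gave 4 genes, 4 of the 10 gave at least as many, and the highest of the others gave 47, in splits that with the context term measure young against aged blood alone, so the difference between the 2 blood libraries gave more genes than that averaged over contexts. Of the 4 splits within contexts the real one gave 4 genes and the others 9, 0 and 0.

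After stroke, classical monocytes of the marrow had lower class II and interferon-stimulated transcripts than at steady state in both ages, as ratios of single libraries without a p-value. The median of the class II genes was −2.36 in young (10 of 11 lower, random lists −0.83 to 0.05) and −2.63 in aged mice (11 of 11), and that of the interferon-stimulated genes was −1.64 (39 of 40 lower, random lists −0.70 to −0.25) and −1.60 (39 of 41). H2-Aa, a class II chain gene, was at −3.78 and −5.26, and the fractalkine receptor gene Cx3cr1 at −4.41 and −5.62. The acute-phase gene Saa3 was at 8.06 in young (4296 and 5 UMIs) and 5.38 in aged mice (3982 and 80 UMIs), and Il1r2 at 5.69 and 6.76. Clusters 3 and 12 held these cells at steady state and clusters 5, 14, 16 and 30 after stroke, where Saa3 leads clusters 5 and 30. Clec4a3 and Ctss, among the leading genes of steady-state cluster 12, also lead unnamed cluster 7 after stroke (91 young and 89 aged cells), outside the class. Unnamed steady-state cluster 23, with the same genes among its leading ones (107 and 126 cells), was outside it too. How far these ratios depend on that naming was not tested. The contrast has the same batch limit as that of neutrophils.

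Rsrp1, which encodes a protein with an arginine- and serine-rich domain, had a higher ratio of aged to young in steady-state marrow in all classes compared there, with log2 ratios of 1.07 in immature neutrophils, 1.10 in dividing pre-neutrophils, 1.23 in classical monocytes and up to 1.37 in megakaryocyte-like cells. After stroke the ratios were −0.22, −0.16 and −0.14 in the first 3 of these. There they were 0.53 in T cells and 0.07 in NK cells, and negative in the other classes compared. In blood they lay between 0.50 (mature neutrophils) and 1.14 (non-classical monocytes). The values after stroke were outside the rule for named genes. No explanation was tested.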
